A study of Homo sapiens with 6 samples.

How the data were processed

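The samples were neural progenitor cells grown from H9, an established human embryonic stem cell line, and collected on day 11 of a differentiation toward midbrain dopamine neurons. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done once for H3K4me3, once for H3K27me3 and once without antibody (input) in each of 2 conditions, Low-Chir and Boost-Chir. The 6 samples were grouped by their titles, which give the mark and the condition. The 4 antibody samples each had 1 peak list. The 2 input samples had no processed file of their own and were not analysed here.

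Reads were processed with cutadapt 1.6, BWA 0.7.12 and Picard and placed on genome build hg19, per the submitters' processing notes, which give no order or settings. The peak caller and its threshold are not given in the sources used here. Peaks were called on each antibody library against the input library of its own condition, per the peak names in the deposited lists, so the lists are per library and nothing was pooled. For each peak the authors' lists hold a start and end, a fold enrichment (a ratio over the local background estimate), a −log10 p-value, a −log10 q-value, a summit position and a score. The deposited score equals 10 times the −log10 q-value cut to a whole number and was not used. Fold enrichment and −log10 q are the authors' own values for a peak and were used to rank or filter peaks within a list. Fold enrichment and the p-value also served to recover depth and reads at the summit, as given below, and these were compared between lists.

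No annotation of hg19 was used here. The only gene table at hand follows another build, GRCh38.p14, and the lists extend to position 249202439 on chromosome 1, beyond the last gene of that table at 248937099. Coordinates were not converted between builds, so no peak was assigned to a gene. Promoter counts, gene lists and the coverage of HOX clusters, which had been fixed before the data were examined, were therefore not computed. The same rules were applied to regions of the genome in their place, and those region rules were written after the lists had been opened. Positions are given on hg19, counted from 1.

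Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 was used for all calculations and matplotlib 3.10.9 for the plots. A peak was counted as shared when a peak of the other condition overlapped it by at least 1 bp. The overlap that chance gives was measured by moving the other list along each chromosome by a random distance, 100 times. Peaks of a list within 3 kb of each other were joined into regions. A region was counted as present in 1 list alone when it held a peak among the top 50% of its list by −log10 q and the other list had no peak within 5 kb. This rule keeps peaks near the calling threshold from counting as a difference. For changes in extent, the peaks of both conditions were joined within 3 kb into loci, and the length covered by peaks was taken for each mark and condition. Loci with a change of at least 2 kb in H3K4me3 or 5 kb in H3K27me3 were counted. The text names the 5 regions per mark and direction that rank first among those present in 1 list alone, by fold enrichment for H3K4me3 and by covered length for H3K27me3. It also names the loci with the greatest change in covered length, taken from the first 10 per mark and direction. The limits of 2 kb and 5 kb and these rules for naming were set after the values had been seen. In a planted test on the Low-Chir list of 44022 H3K4me3 peaks, the rule found 200 of 200 planted gains and 200 of 200 planted losses. On the list of 25725 H3K27me3 peaks it also found 200 of 200 of each. The planted changes were strong and isolated, and the second list was a copy of the first with slightly moved edges. The test thus checks the code and not how the rule behaves between 2 real libraries.

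With 1 library per mark and condition there is no replicate, so no p-value was computed and no difference has a replicate check. Shares of regions carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat regions as independent, which neighbouring regions are not. The lists state no read depth. The fold enrichment and p-value of a peak were solved for the reads at its summit and its background, assuming a fold of (reads + 1) over (background + 1) and a Poisson tail for p. The solution returned the deposited −log10 p within 0.001 for 100% of the peaks of each list, with reads in whole multiples of 1 step. The genome-wide background in units of that step, which is proportional to depth, was 2.21 for H3K4me3 in Low-Chir and 2.67 in Boost-Chir, and 3.12 and 3.03 for H3K27me3. The Boost-Chir H3K4me3 library was thus 1.21 times as deep as its Low-Chir partner, and the Boost-Chir H3K27me3 library 0.971 times. On 2 simulated depths this procedure returned 100% of the pile-ups. The simulated peaks were made with the same formulas, so this checks the code and not the assumptions. Alternatives to the overlap rule, the strength of peaks, the joining distance, the size of change and the depth were computed.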

Results

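H3K4me3, a mark of active and poised promoters, and H3K27me3, the mark deposited by Polycomb repressive complexes, were profiled by ChIP-seq in neural progenitors on day 11 of midbrain dopamine differentiation. The comparison was between Low-Chir and Boost-Chir cultures. CHIR99021 inhibits the kinase GSK3 and thereby activates canonical WNT signalling. Cultures started in 0.7 µM of the compound, Boost-Chir cultures received 7.5 µM from day 4 to day 10, and medium with 3 µM was used from day 10. The labels list 0.7 µM as the lowest concentration used from day 4 and do not state which one Low-Chir cultures received. Each mark was measured in 1 library per condition, so every difference below lacks a replicate check. The H3K4me3 lists held 44022 peaks in Low-Chir and 46793 in Boost-Chir, with a median of 17 and 18 reads at the summit. The H3K27me3 lists held 25725 and 26260 peaks, with a median of 20 and 18 reads. Peaks were not assigned to genes, and positions are on hg19.

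H3K4me3 occupied largely the same places in both conditions but spread over more of the genome in Boost-Chir. Of the top 25% of peaks by −log10 q, 99.95% of those in Low-Chir and 99.89% of those in Boost-Chir were overlapped by a peak of the other condition. The covered length was 38.5 Mb in Low-Chir and 49.7 Mb in Boost-Chir, a ratio of 1.29, for a peak number that differed 1.06-fold. Regions with at least 4 kb under peaks numbered 2494 in Low-Chir and 4742 in Boost-Chir, and those with at least 10 kb numbered 91 and 224. Over all peaks, 83.6% of the Low-Chir list and 59.6% of the Boost-Chir list were shared, against 2.85% and 2.46% by chance. Once peaks within 3 kb were joined, the shared percentages of joined regions were 93.6% and 90.4%, so most Boost-Chir regions met a Low-Chir region although many single peaks did not. The Boost-Chir library was 1.21 times as deep, and a deeper library gives more and wider peaks at the same threshold.

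**Figure D1:**
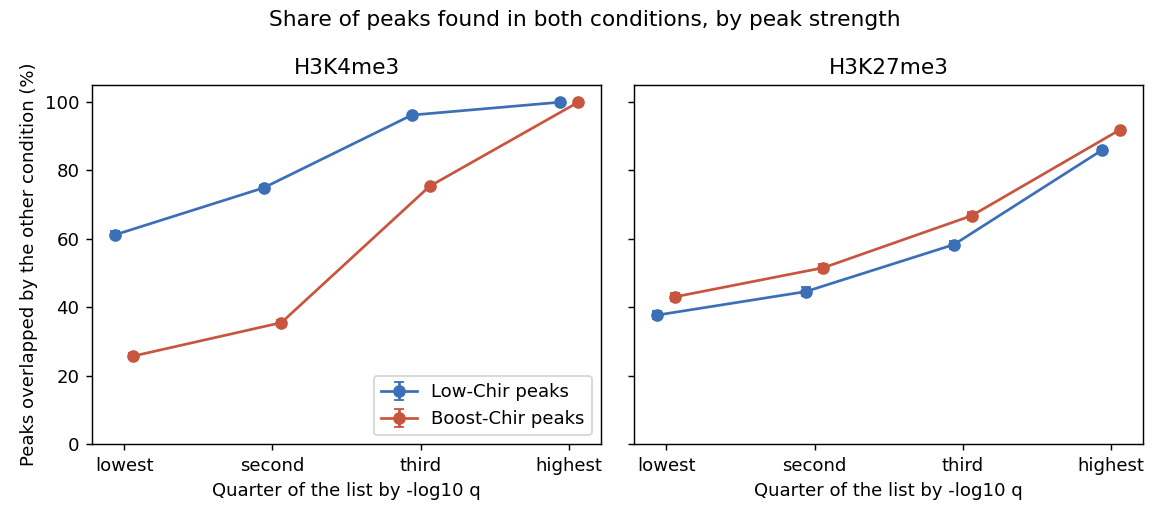
Percentage of peaks (vertical axis) overlapped by at least 1 bp by a peak of the other condition, for each 25% of a list ranked by −log10 q (horizontal axis). Points are 1 library each and bars are exact 95% binomial intervals, mostly smaller than the points; in the lowest 25% of H3K4me3 peaks the share was 61.2% for Low-Chir and 25.8% for Boost-Chir, while in the highest 25% they were 99.95% and 99.89%.

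New H3K4me3 regions were few. Of 14035 strong Boost-Chir regions, 320 (2.28%, exact 95% interval 2.04 to 2.54) had no Low-Chir peak within 5 kb. In the other direction the number was 77 of 13267 (0.580%, 0.458 to 0.725). Each list had its own cut, a −log10 q of 6.30 in Boost-Chir and 7.32 in Low-Chir, so weaker peaks could qualify in Boost-Chir. Ranked by fold enrichment, the first Boost-Chir region lay on chromosome 7 at 12753370 to 12755455, with an enrichment of 11.2-fold. The next lay on chromosome 12 at 130526629 to 130531096, at 11.1-fold, where 2059 bp carried H3K27me3 in Low-Chir and 0 bp in Boost-Chir. A region on chromosome 19 at 46633772 to 46636620 had 10.9-fold enrichment and no H3K27me3 in either condition. On chromosome 7 at 155258133 to 155264429, a Boost-Chir region of 6297 bp held 5805 bp under H3K4me3 peaks, the highest at 10.8-fold. H3K27me3 peaks covered all 6297 bp in Low-Chir and 450 bp in Boost-Chir. The fifth region was on chromosome 9 at 96844642 to 96849196, at 10.1-fold. Of all 320 regions, 55 (17.2%, 13.2 to 21.8) held H3K27me3 in Low-Chir and 51 (15.9%, 12.1 to 20.4) in Boost-Chir, against 18.8% and 18.4% of the 14035 strong regions. Low-Chir regions without a Boost-Chir partner were led by chromosome 4 at 113970824 to 113973390 (8.72-fold), chromosome 8 at 40011016 to 40014230 (8.35-fold) and chromosome 12 at 92860524 to 92862434 (8.28-fold). Regions on chromosome 13 at 96056004 to 96056660 (7.61-fold) and at 33922645 to 33924998 (7.16-fold) followed.

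H3K4me3 also differed in breadth. Among 14475 loci marked in both conditions, the Boost-Chir length was 1.28 times the Low-Chir length at the median, a shift of 626 bp, and individual loci are to be read against that shift. Of all 16580 loci, 1191 were at least 2 kb longer in Boost-Chir and 57 at least 2 kb shorter. The greatest extension was on chromosome 3 at 11645480 to 11687358, where 6.41 kb of H3K4me3 in Low-Chir stood against 33.7 kb in Boost-Chir, a ratio of 5.26. Another 4 loci were over 3 times as long and carried less H3K27me3 in Boost-Chir. These were chromosome 10 at 102489438 to 102514179 (4.92 to 19.4 kb), chromosome 2 at 171561391 to 171582575 (5.84 to 18.1 kb), chromosome 10 at 54066710 to 54080504 (2.27 to 13.1 kb) and chromosome 9 at 37021803 to 37037526 (3.26 to 12.9 kb). The locus on chromosome 2 at 119582524 to 119616457 was already broad, at 19.0 kb, and reached 32.2 kb. Without H3K27me3 in either list, chromosome 17 at 63537571 to 63558621 went from 7.53 to 17.4 kb and chromosome 16 at 50581128 to 50595082 from 3.43 to 12.5 kb. On chromosome 4 at 109078185 to 109095365 the length went from 6.92 to 15.3 kb. On chromosome 17 at 7107476 to 7160489 the ratio was 1.40, close to the general shift, and the extension of 9778 bp fell to 4474 bp with the top 50% of each list.

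The loci with less H3K4me3 in Boost-Chir ran against that general widening. The first was on chromosome X at 25018374 to 25039664, with 18.2 kb in Low-Chir and 3.47 kb in Boost-Chir, while H3K27me3 there covered 0.812 kb in Low-Chir and 19.5 kb in Boost-Chir. Chromosome 1 at 50881934 to 50896320 had 11.3 and 0.788 kb of H3K4me3, and chromosome 11 at 31825941 to 31839986 had 9.65 and 2.52 kb. Both of these loci were under H3K27me3 over nearly their whole length in both conditions, with 13.9 and 14.2 kb at the first and 13.3 and 13.2 kb at the second. On chromosome 20 at 21486083 to 21504092, H3K4me3 covered 13.4 kb in Low-Chir and 6.70 kb in Boost-Chir and H3K27me3 8.04 and 16.8 kb. Chromosome 1 at 197878396 to 197890627 (6.89 and 1.97 kb of H3K4me3) and chromosome 11 at 20177082 to 20186787 (7.31 and 2.62 kb) followed. Of the 57 loci at least 2 kb shorter, 38 held H3K27me3 peaks, which were longer in Boost-Chir at 29 (76.3%, 59.8 to 88.6) and shorter at 8. Some of the 29 differences were small, such as 332 bp on chromosome 1 at 50881934 and 236 bp at 197878396. Among H3K4me3 loci that changed by less than 2 kb, H3K27me3 was longer at 38.1% (36.6 to 39.7) of 3812. That share may be low, since H3K27me3 was counted only within each H3K4me3 locus and a short locus can cut a change off.

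H3K27me3 covered less of the genome in Boost-Chir. The covered length was 20.9 Mb in Low-Chir and 18.8 Mb in Boost-Chir, a ratio of 0.901, with 1.02 times as many peaks and 0.971 times the depth. Boost-Chir peaks were also slightly weaker, with a median fold of 4.20 against 4.29 and a median −log10 q of 4.99 against 5.41. Such list medians say little about the immunoprecipitation. For H3K4me3 the median fold was also lower in Boost-Chir, at 4.50 against 5.00. Yet H3K4me3 reads above background per unit of depth were higher there, with a median ratio of 1.09 at loci in both lists. Enrichment per unit of depth was not compared for H3K27me3, so a weaker Boost-Chir immunoprecipitation stays open for this and the following differences. Regions with at least 10 kb under peaks numbered 413 in Low-Chir and 352 in Boost-Chir. Peaks overlapped by the other condition made up 56.9% of the Low-Chir list and 63.7% of the Boost-Chir list, against 1.14% and 1.19% by chance. Among the top 25% of peaks these shares were 86.0% and 91.9%. Strong regions present in 1 list alone numbered 492 of 4249 in Low-Chir (11.6%, 10.6 to 12.6) and 459 of 4199 in Boost-Chir (10.9%, 10.0 to 11.9). By any peak the order turned, with 1445 in Low-Chir and 1587 in Boost-Chir. Without joining it held and the gap widened, with 927 and 654. At the median of 4499 loci marked in both, the Boost-Chir length was 0.917 times that of Low-Chir.

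The domains present in Low-Chir alone were led by chromosome 8 at 25817547 to 25843924, with 16.6 kb under 24 peaks. Next came chromosome 21 at 44757998 to 44787384 with 12350 bp and chromosome 4 at 124770661 to 124786381 with 10730 bp. On chromosome 2 at 171563332 to 171576757, 9.83 kb of H3K27me3 in Low-Chir had no counterpart in Boost-Chir, while H3K4me3 covered 5.84 kb in Low-Chir and 12.8 kb in Boost-Chir. A domain on chromosome 4 at 3870390 to 3881946 with 7897 bp of H3K27me3 had 1764 bp of H3K4me3 in Boost-Chir alone. Domains of the Boost-Chir list alone were led by chromosome 5 at 72544372 to 72565843 with 11.4 kb and chromosome 1 at 175528470 to 175549807 with 10.4 kb, neither with an H3K4me3 peak. Chromosome 5 at 135524632 to 135537053 (6477 bp), chromosome 1 at 165201473 to 165224852 (5994 bp) and chromosome 15 at 99672847 to 99688139 (4665 bp) followed. The rule asks only for no Low-Chir peak within 5 kb, and the leading domain lay near H3K27me3 of both lists. An H3K27me3 locus further along chromosome 5, at 72581532 to 72611876, had 13.2 kb in Low-Chir and 22.7 kb in Boost-Chir.

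In extent, reductions of H3K27me3 outnumbered extensions: 96 loci were at least 5 kb shorter in Boost-Chir and 24 at least 5 kb longer. The greatest reduction was on chromosome 10 at 102400112 to 102524949, from 101.8 kb in Low-Chir to 56.0 kb in Boost-Chir. Chromosome 7 at 155229116 to 155329802 had 82.1 and 39.4 kb, and chromosome 3 at 147070151 to 147145863 had 72.8 and 38.5 kb. H3K4me3 at these loci covered 6.58 and 24.0 kb, 1.24 and 20.2 kb, and 9.34 and 24.955 kb respectively, in Low-Chir and Boost-Chir. Chromosome 2 at 119585593 to 119620873 went from 28.0 to 4.28 kb of H3K27me3 and chromosome 7 at 42100074 to 42149545 from 31.1 to 0.970 kb. The loci that were longer in Boost-Chir included chromosome X at 25016053 to 25045328 (2.72 and 24.3 kb), chromosome 8 at 139255554 to 139290423 (1.59 and 18.1 kb) and chromosome 7 at 155589576 to 155607595 (0.200 and 11.6 kb). At the last of these, H3K4me3 covered 8.81 kb in Low-Chir and 5.47 kb in Boost-Chir.

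**Figure D2:**
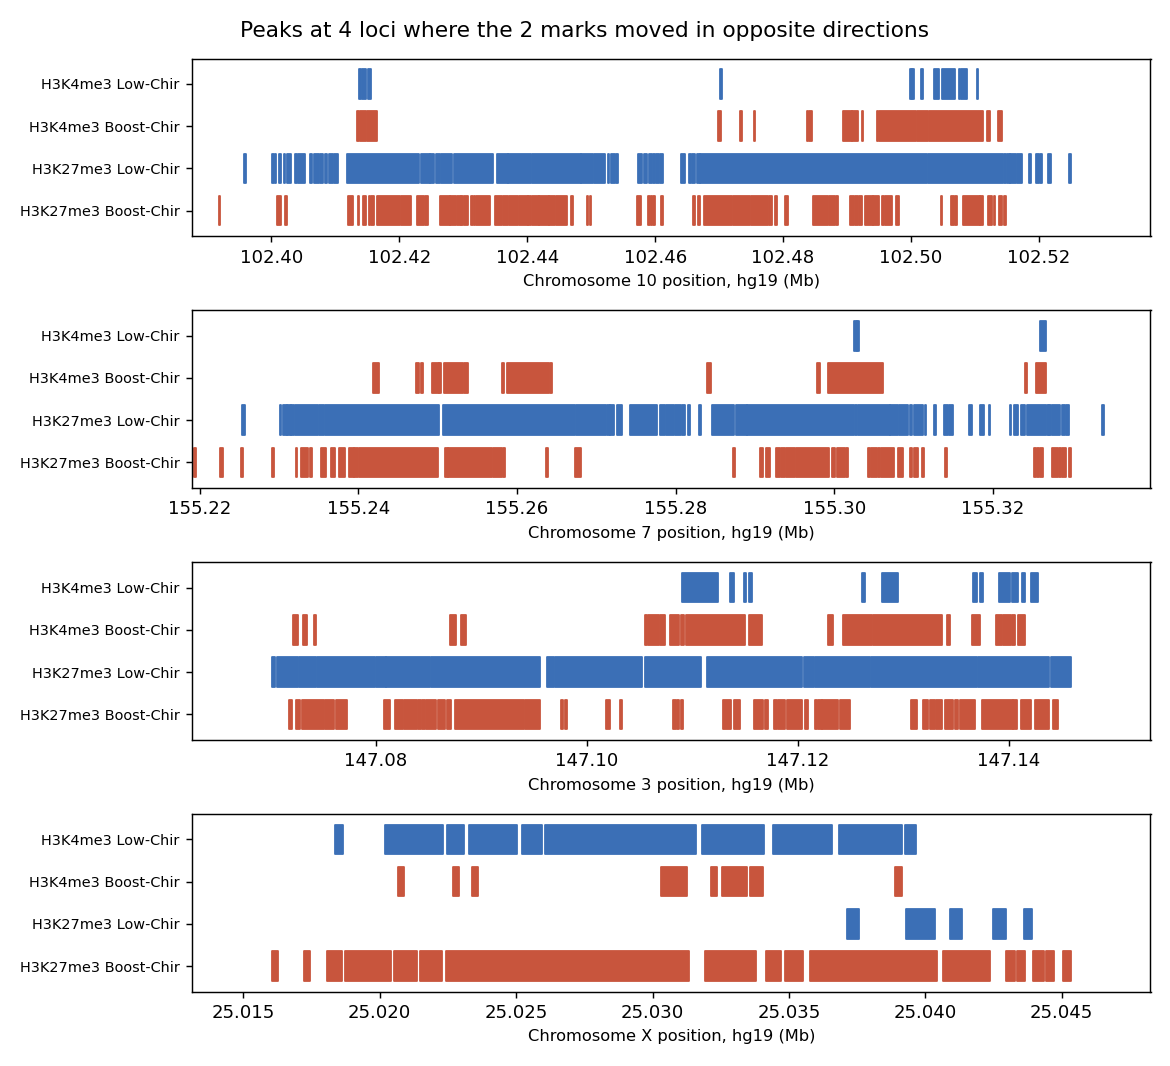
Deposited peaks of H3K4me3 and H3K27me3 (rows) in Low-Chir (blue) and Boost-Chir (red) along 4 loci, with hg19 position in Mb on the horizontal axis; each bar is a peak from 1 library and its height carries no value. On chromosomes 10, 7 and 3 H3K27me3 covered less and H3K4me3 more in Boost-Chir, and on chromosome X H3K27me3 went from 2.72 to 24.3 kb and H3K4me3 from 18.2 to 3.47 kb.

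Both marks were measured in the same conditions, so their changes could be set side by side. Of the 96 loci with at least 5 kb less H3K27me3 in Boost-Chir, 61 held an H3K4me3 peak, and H3K4me3 was longer in Boost-Chir at 55 of these (90.2%, 79.8 to 96.3). At H3K27me3 loci that changed by less than 5 kb, the share was 58.2% (56.6 to 59.8) of 3674. That reference may be low, since H3K4me3 was counted only within each H3K27me3 locus and a short locus can cut a change off. Over all 16580 H3K4me3 loci, 13213 were longer in Boost-Chir, so this was the usual direction. Against that reference the excess at the 61 loci is smaller than against the 58.2%. Of the 24 loci with at least 5 kb more H3K27me3, 10 held an H3K4me3 peak, which was shorter in Boost-Chir at 8 (80%, 44.4 to 97.48). Counting only H3K4me3 changes of at least 2 kb, 30 loci had less H3K27me3 and more H3K4me3 in Boost-Chir, 3 showed the reverse, and 0 loci had more or less of both marks past these limits. Seen from H3K4me3, 168 of the 1191 extended loci held H3K27me3, and it was shorter in Boost-Chir at 147 of them (87.5%, 81.5 to 92.1). Among H3K4me3 loci that changed by less than 2 kb, it was shorter at 54.4% (52.8 to 56.0) of 3812. This reference may be low too, since H3K27me3 was counted only within each H3K4me3 locus. Regions in 1 list alone were compared only by presence of the other mark, which misses changes in length, and by presence they showed no clear opposition. The named regions of this kind that held the other mark did differ in opposite directions by length. Length was not compared over all of them. At the 77 H3K4me3 regions of Low-Chir alone, H3K27me3 was present at 18 in Low-Chir and 15 in Boost-Chir. H3K4me3 was present at 125 (27.2%) and 142 (30.9%) of the 459 H3K27me3 regions of Boost-Chir alone, and at 164 (33.3%) and 180 (36.6%) of the 492 of Low-Chir alone. Among all strong H3K27me3 regions these shares were higher, at 57.5% and 58.7% for the Boost-Chir list and 60.4% and 60.6% for the Low-Chir list. The mean H3K4me3 change at the 96 loci was 2060 bp, against a mean of 225 bp and a highest value of 893 bp in 10000 random sets of H3K27me3 loci matched on H3K4me3 length.

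**Figure D3:**
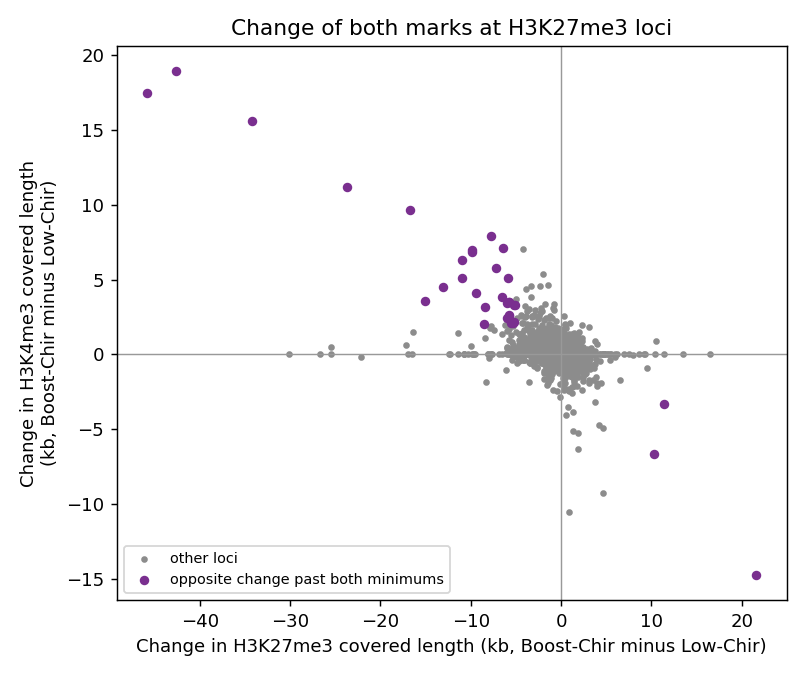
Change in the length covered by H3K4me3 (vertical axis, kb) against the change in H3K27me3 (horizontal axis, kb), Boost-Chir minus Low-Chir, with 1 point per H3K27me3 locus and 1 library per mark and condition. Purple points are the 30 loci with at least 5 kb less H3K27me3 and at least 2 kb more H3K4me3, at the upper left, and the 3 loci with the reverse, at the lower right.

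The number of regions that carried both marks hardly differed. An H3K4me3 region, joined within 3 kb, was counted when at least 1 bp of H3K27me3 lay anywhere between its ends. Peaks of the 2 marks thus need not overlap. Such bivalent regions, a state common at developmental promoters in stem cells and progenitors, made up 3191 of 15614 H3K4me3 regions in Low-Chir (20.4%, 19.8 to 21.1) and 3145 of 16002 in Boost-Chir (19.7%, 19.0 to 20.3), against 1.86% and 2.05% of such regions by chance. Among 16580 H3K4me3 loci, 2586 were bivalent in both lists. By any peak, 522 had both marks in Low-Chir and H3K4me3 only in Boost-Chir, and 428 the reverse, but these counts include peaks near the calling threshold. With a peak in the top 50% of 1 list and none of the other within 5 kb, 159 and 128 remained. For H3K4me3 absent beside H3K27me3, 185 loci had both marks in Low-Chir alone and 166 in Boost-Chir alone, of which 11 and 42 remained under that rule. Peaks of both marks at 1 locus do not show that both sit on the same chromosomes, since a bulk culture can hold cells of either state. With the top 50% of each list the Boost-Chir number of bivalent regions was the higher one, at 1790 against 1525. Asking for at least 500 bp of each mark left 1879 bivalent regions in Low-Chir and 1864 in Boost-Chir.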

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

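The alternatives for the overlap of peak sets were fixed before the data were examined, and those for regions, loci, bivalent regions and depth were chosen after seeing the data. No paired analysis was possible because each mark and condition has 1 library. Alternatives fixed in advance for promoter windows, transcript starts, gene classes, gene lists and HOX clusters were not run, since no peak was assigned to a gene. The overlap of peak sets depended on the rule. For H3K4me3 peaks of Low-Chir and Boost-Chir in turn, the shared percentage was 76.8 and 49.0 with 50% of the peak covered, 39.4 and 37.1 with reciprocal overlap of 50%, and 94.6 and 74.3 between the top 50% of the lists. It was 98.1 and 87.4 for the top 50% against all peaks, 93.6 and 90.4 with peaks within 3 kb joined, 82.6 and 61.8 with the same number of peaks, and 83.1 and 60.5 at the depth of the Low-Chir library. For H3K27me3 it was 42.6 and 52.1 with 50% covered, 21.3 and 20.9 with reciprocal overlap, 72.0 and 79.0 for the top 50% against all peaks, 65.5 for joined Low-Chir peaks, and 65.8 for Boost-Chir between the top 50% of the lists. Regions in 1 list alone followed the strength asked of the peak. With any peak, H3K4me3 gave 1159 in Boost-Chir and 623 in Low-Chir, and H3K27me3 gave 1587 and 1445. With the top 25%, these numbers were 8 and 0, and 85 and 122. Without joining, H3K27me3 regions numbered 927 in Low-Chir alone and 654 in Boost-Chir alone, further apart than the 492 and 459 of the main rule. Boost-Chir stayed ahead for H3K4me3 under all 8 of these alternatives, whereas the order for H3K27me3 turned with any peak and kept its side under the other 7. For H3K27me3, 1 of those 7, the scaling to depth, dropped 0 peaks and only repeated the main values. Bivalent regions in Low-Chir and Boost-Chir numbered 1525 and 1790 with the top 50%, 5906 and 5599 without joining, and 1879 and 1864 with at least 500 bp of each mark. Asking for a peak in the top 50% of 1 list and none of the other within 5 kb left 159 of 522 loci with H3K27me3 beside H3K4me3 in Low-Chir alone and 128 of 428 in Boost-Chir alone. For H3K4me3 beside H3K27me3, 11 of 185 and 42 of 166 were left, which turned their order. Loci with more and less H3K27me3 numbered 190 and 476 at 2 kb and 8 and 27 at 10 kb, and those with more were 12 when joined within 1 kb and 38 within 10 kb. Loci with more and less H3K4me3 numbered 4931 and 239 at 1 kb and 68 and 4 at 5 kb. Loci with longer H3K27me3 and shorter H3K4me3 numbered 7 when joined within 10 kb. The 40 loci ranked by change kept their direction with the top 50% and with the same number of peaks, and 2 of them moved by over 1.5 times with the top 50%. These were chromosome 17 at 7107476, where the H3K4me3 change went from 9778 to 4474 bp, and chromosome 2 at 121617532, where the H3K27me3 change went from -22209 to -14170 bp. Fewer or smaller changes pass a stricter limit by construction, and for the remaining values the cause was not tested. Depth limits the weakest peaks, which most often lacked a partner, and covered length cannot be corrected for depth from peak lists.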

Other observations

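The tests of general widening, of copy number and of neighbouring loci in this part were chosen only after the result was seen. Not all loci that lost H3K27me3 extent carried H3K4me3. Of the 96 loci at least 5 kb shorter in Boost-Chir, 35 had no H3K4me3 peak in either list. They included chromosome 7 at 42100074 to 42149545 (31.1 kb in Low-Chir and 0.970 kb in Boost-Chir), chromosome 10 at 116405900 to 116457523 (37.1 and 10.4 kb) and chromosome 2 at 121776421 to 121837667 (44.6 and 19.1 kb). Chromosome 7 at 68682477 to 68712396 had 19.7 and 2.83 kb, and chromosome 16 at 79911885 to 79939142 had 12.6 and 0.200 kb.

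Some of the loci with less H3K27me3 lay in runs. On chromosome 2 a locus at 121424704 to 121474565 (22.3 kb in Low-Chir and 11.6 kb in Boost-Chir) was followed by those at 121617532 to 121662529 (22.4 and 0.211 kb) and 121776421 to 121837667. On chromosome 9 loci at 36853234 to 36882898 (17.4 and 7.72 kb), 36979209 to 37007608 (19.5 and 9.53 kb) and 37017952 to 37043371 (20.7 and 3.95 kb) formed another run.

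Of the 96 loci, 29 had another such locus within 500 kb, against a mean of 9.67 and a highest value of 28 in 10000 random sets of H3K27me3 loci matched on H3K27me3 length. With a match on length in 50 bins in place of 10, the 29 stood against a highest value of 27, which argues against the length of the loci as the whole cause. With all H3K27me3 loci joined within 50 kb first, to count pieces of 1 domain once, 35 of 134 had such a neighbour, against a highest value of 32. That test replaced one on the gap between edges, whose value had been seen, because short pieces can lie in such a gap. Domains with pieces further apart, and differences between single libraries, stay open.

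More H3K4me3 regions were found in the Boost-Chir list alone (320) than in the Low-Chir list alone (77). With the Boost-Chir peaks scaled to the depth of the Low-Chir library, the counts were 273 and 79. The scaling dropped 1239 weak Boost-Chir peaks, and the others kept their deposited −log10 q. It could therefore hardly remove a strong region, and it cannot decide whether depth was the cause. Reads above background at the summit, per unit of depth, were also higher in Boost-Chir, with a median ratio of 1.09 over 14475 loci in both lists. After dividing by that ratio too, the counts were 253 and 81, the same as with the same number of peaks from each list. Both of these settings shorten the Boost-Chir list and so raise its cut as well. The scaling lowers summits only to choose the peaks to drop, and it neither narrows peaks nor adds counting noise. Depth, and a difference between the cultures, their cell mixtures or 2 single immunoprecipitations, stay open.

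H3K4me3 was longer where H3K27me3 was shorter. General widening of H3K4me3 in the Boost-Chir list would give these loci the change of other loci, but their mean of 2060 bp lay above all 10000 random sets, whose highest was 893 bp. The sets were matched on H3K4me3 length but not on locus length, which bounds how much widening a locus can show. Fewer copies of these loci in the Boost-Chir culture could shorten both marks, and H3K4me3 was shorter at 9.84% (3.70 to 20.2) of the 61 that carried it. This cannot decide on copy number, since peaks were called against the input of their own condition and general widening could hide a modest loss. The input libraries were not analysed, and the 35 loci without H3K4me3 give no value. A change within cells, a different mixture of cells, copy number and differences between single libraries stay open, and bulk peak lists do not separate these.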
